A study of Mus musculus with 18 samples.

How the data were processed

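ChIP-seq of mouse liver was deposited as 18 peak lists, 1 per library, for CTCF (2 WT, 2 KO), PPARg (2 WT, 2 KO), H3K27ac (3 WT, 3 KO), H3K4me3 (1 WT, 1 KO) and H3K27me3 (1 WT, 1 KO). Per the labels, WT is CTCF fl/fl without Alb-Cre and KO is CTCF fl/fl with Alb-Cre, all C57BL/6 at 8 weeks. The submitters' processing notes name BWA 0.7.12, Picard 1.77, MACS2 2.1.2 and deepTools 3.1.3 with build mm10, and do not state the control used for peak calling. The authors gave each peak a fold enrichment over background, which is a ratio, and a −log10 p and −log10 q. They also gave a deposited whole-number score, about 10 times the −log10 q, which was not used. The lowest −log10 q in the files was near 1 for H3K27ac and H3K27me3 (q of 0.1), near 1.3 for H3K4me3 and PPARg WT 4 (q of 0.05) and near 3 for CTCF and the other 3 PPARg lists (q of 0.001). The deposited CTCF lists had patches and blacklisted regions removed per their names, and the PPARg lists had not been freed of blacklisted regions. Per the labels, CTCF and PPARg WT 2, KO 7 and KO 8 were tagmentation libraries of fasted males. The other libraries, PPARg WT 4 among them, were made with a ligation kit from animals of unstated sex, and their growth protocol text describes neural stem cells, although source and tissue are liver.

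Peaks on chromosomes 1 to 19, X and Y were kept, and H3K4me3 intervals listed once per summit were collapsed. Read depth cannot be had from peak lists. The number of peaks and the covered length are given instead, and intervals on shares (Wilson, 95%) cover counting error over sites alone. For each factor the lists were merged into regions by an overlap of at least 1 bp. A CTCF site was lost if called in both WT and neither KO, retained if called in all 4, and gained if called in both KO and neither WT, and PPARg and H3K27ac regions were classed in the same way. Sites were ranked by −log10 q within each list.

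Genes were the 21883 protein-coding genes of the RefSeq annotation of the same build, which came without strand. The design, fixed before the data were examined, had asked for windows around transcription start sites. These were replaced by windows around the gene span (5 kb for H3K27ac, H3K27me3 and CTCF gene lists, 10 kb for PPARg), by windows of 1 kb at both gene ends for CTCF features, and by 1 kb at both ends for H3K4me3. The H3K27ac measure was the percentage of the gene span with 5 kb either side that peaks covered. The window of 1 kb around a start site was replaced by 1 kb around the end that H3K4me3 marks, which 11165 genes have. No scaling between libraries was applied in the main values.

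H3K27ac values were fitted with limma 3.58.1 in R 4.3.3 (3 KO against 3 WT, genes without variation left out, Benjamini-Hochberg adjusted p under 0.05). The 17 gene lists were tested with limma camera (preset correlation 0.01, then estimated) and fry. They covered PPARG targets and lipid droplet, fatty acid and triglyceride synthesis, fatty acid oxidation and ketogenesis, hepatocyte identity, bile acid and cholesterol metabolism, xenobiotic metabolism, fetal liver and hepatocyte stress, cell cycle, clustered protocadherins, Hox clusters, architectural proteins and housekeeping. The last 5 were markers of Kupffer cells and macrophages, stellate cells and fibrosis, endothelium, cholangiocytes and lymphocytes. Of 361 entries 359 matched a gene, by symbol or else by synonym. The entry H19, not itself among the protein-coding genes, was matched to Nckap1 through a synonym. The CTCF, PPARg, H3K4me3 and H3K27me3 values of the fetal liver and stress list therefore include Nckap1 in its place. Sites and genes were compared with Fisher's exact test in scipy 1.17.1 and Python 3.11.15, adjusted over each family by Benjamini-Hochberg. Mean changes across genes were compared by a permutation test of 100000 resamples. With 1 library per genotype no test was run, and mean changes of lists were placed among 10000 random lists of equal size, in which each member was replaced by a gene of like mean covered length in both libraries (within a window of 200 ranks).

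Genes were named by a rule. For H3K27ac the rule took the 10 largest rises and the 10 largest falls past the test. Since none passed, it was filled with genes whose 3 values of 1 genotype all lay beyond those of the other, by size of change. For CTCF the rule took the genes nearest the 10 lost, 5 retained and 5 gained sites with the best mean rank, and for PPARg those nearest the 10 KO-only, 5 shared and 5 WT-only sites. For H3K4me3 and H3K27me3 it took the 5 largest gains and losses, and from each list the members past a test or else up to 4 in list order. Ctcf and Pparg were always named. Not every site the rule took is described. The rule did not cover WT-only and KO-only H3K27ac regions, whose genes are all list members within 5 kb and some of those nearest the widest regions, chosen after their values were seen.

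Alternatives tried were stricter −log10 q thresholds (10 for CTCF and PPARg, 5 for histone marks), an overlap of 50% of the shorter peak, peaks within 1 kb merged first, lists of equal length, other windows and backgrounds, division by total covered length, filters on covered length, limma-trend, the label's replicate number as a block, PPARg with the tagmentation libraries alone, and each library left out in turn. Lists of equal covered length, a common −log10 q of 3 for PPARg, windows at gene ends for PPARg, 5 kb around the marked gene end and backgrounds matched on gene length were added after the data were seen. The limma fit was tested on simulated data: of 50 genes each shifted by 10, 20, 40 and 60 percentage points among 14876, it called 17, 33, 48 and 46, with 9 unchanged genes called and 0 called when nothing was shifted. The overlap code matched direct counting in all of 500 simulated windows, and the permutation test gave p under 0.05 in 5% of 200 simulated sets without a difference.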

Results

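Chromatin of the liver was profiled by ChIP-seq in 8-week-old C57BL/6 mice that carried floxed Ctcf alleles. Mice with the Alb-Cre transgene (KO), which expresses the recombinase from the albumin promoter and so acts in hepatocytes, were set against mice without it (WT). CTCF is the zinc-finger protein that binds insulators and domain boundaries, and PPARg is a nuclear receptor that drives fat storage genes. The 18 libraries covered 5 targets. CTCF and PPARg had 2 WT and 2 KO libraries each, H3K27ac (a mark of active promoters and enhancers) had 3 and 3, and H3K4me3 (active promoters) and H3K27me3 (Polycomb repression) had 1 and 1. The values are peak lists called in each library on build mm10, so read depth is unknown and the number of peaks and the base pairs they cover stand in its place.

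The CTCF lists held 27585 (WT164), 24566 (WT165), 18597 (KO160) and 20323 peaks (KO163). The PPARg lists held 16617 (WT 4), 15520 (WT 2), 27439 (KO 7) and 26349 peaks (KO 8). The H3K27ac lists held 37312, 40545 and 34324 peaks in WT 1, 2 and 4 and 35480, 39092 and 51311 in KO 2, 3 and 4. KO 4 stood apart, with 126 Mb covered against 78.2 to 91.5 Mb in the other 5 libraries. H3K4me3 had 16341 peaks in WT and 17402 in KO, and H3K27me3 had 8131 and 9216. The mean number of peaks in KO divided by that in WT was 0.746 for CTCF, 1.67 for PPARg and 1.12 for H3K27ac. The two-sided exact permutation p was 0.333 for CTCF and PPARg, the smallest that 2 against 2 libraries can give, and 0.6 for H3K27ac, where 0.1 is the smallest.

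CTCF was compared between genotypes to see which of its binding sites lost their call when the protein was deleted from hepatocytes. Most sites kept a peak in KO liver. Of 22044 sites called in both WT libraries, KO160 called 76.6% (95% Wilson interval 76.1 to 77.2) and KO163 called 82.2% (81.7 to 82.7). Both KO libraries called 15934 of them (72.3%), neither called 2965 (13.5%, 13.0 to 13.9), and 1 of the 2 called 3145. In turn, 50 sites were called in both KO and neither WT. With all lists shortened to equal length 649 sites were lost (3.99%) and 390 gained. The interval covers counting error alone, and an exact permutation test of 2 against 2 libraries cannot go below 0.333. For comparison, of all peaks of WT164 81.0% overlapped a peak of WT165, 63.7% one of KO160 and 69.6% one of KO163. Of all peaks of WT165 92.2% overlapped a peak of WT164, 71.0% one of KO160 and 76.7% one of KO163.

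Lost sites with a high WT rank lay between genes near Gm10479, Erc2, Jph3 and Ccdc87, 96.5 kb from Poteg, and inside the spans of Mcm3ap, Map7, Prss22 and Aff3. The Mcm3ap site (chromosome 10, 76513106 to 76514038) had fold enrichments of 14.5 and 8.32 in the WT libraries. The sites with the best WT rank that every library called lay near Nemp1, Nipsnap2 and Kdm3b and inside Ctif and Dnah17. At the Nemp1 site (chromosome 10, 127673988 to 127675497) the fold enrichment was 51.7 and 60.4 in WT and 44.6 and 39.9 in KO. The gained sites with the best KO rank lay at Arsb, Itprip, Trappc9 and Cxadr and 124 kb from Haao, with fold enrichments of 4.59 to 9.55. Ctcf itself, with 5 kb either side, held 3 CTCF peaks in each of the 4 libraries.

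Lost sites were the weak ones. Their median percentile in the WT lists was 22.9, against 68.0 for sites retained in all 4 libraries. In the weakest 10% of WT sites 60.9% were lost (58.8 to 62.9), and in the strongest 10% 0 of 2205 were lost (upper limit 0.174%). Lost sites lay less often than retained sites within 1 kb of a gene end (11.1% against 15.7%, odds ratio 0.667, adjusted p = 7.8e-11 by two-sided Fisher's exact test). They also overlapped less often a WT H3K4me3 peak (7.02% against 10.3%, odds ratio 0.659, adjusted p = 2.8e-08) and an H3K27ac region of all 3 WT (17.6% against 20.6%, odds ratio 0.821, adjusted p = 0.00018). A WT H3K27me3 peak overlapped 5 lost and 77 retained sites (odds ratio 0.348, adjusted p = 0.014). Sites are not independent replicates. Lost and retained sites were not matched for strength or width, so these differences in location cannot be told apart from the weakness of lost sites. Without KO160 the H3K27ac difference did not pass (odds ratio 0.939, adjusted p = 0.164), and the H3K27me3 difference did not pass with any 1 of the 4 libraries left out (odds ratios 0.526 to 0.681). Leaving out a library loosens the rule, and the number of lost sites was then 4637 without WT164, 7130 without WT165 and 5163 without KO163, with 272, 97 and 502 gained, and 732 gained without KO160.

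**Figure D1:**
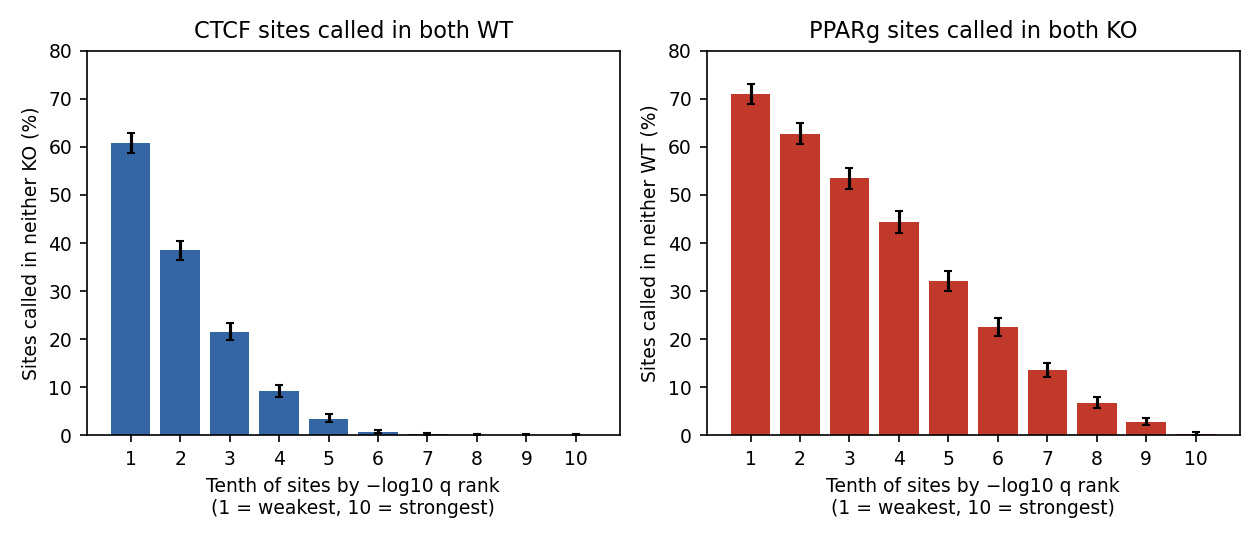
The left panel plots the percentage of CTCF sites called in both WT libraries that neither KO library called, and the right panel the percentage of PPARg sites called in both KO libraries that neither WT library called, in 10 bins of −log10 q rank with 95% Wilson intervals. The share went from 60.9% in the weakest to 0% in the strongest bin for CTCF, and from 71.0% to 0.255% for PPARg.

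The gene groups were also compared by the share of lost sites among the lost and retained sites within 5 kb of their genes, where other genes gave about 15.7%. In the clustered protocadherins, cell surface adhesion genes whose promoter choice uses CTCF, 4 of the 8 sites were lost (Fisher's exact p = 0.0249, adjusted p = 0.25). Fatty acid and triglyceride synthesis genes lost 10 of 33 sites (adjusted p = 0.25) and fatty acid oxidation genes 8 of 28 (adjusted p = 0.391). None of the 17 lists passed the adjusted threshold, and 2 had an unadjusted p under 0.05. The share lost was 15.4% for hepatocyte identity, 25% for bile acid and cholesterol, 17.6% for xenobiotic and 4.76% for PPARG target genes. It was 15.4% for fetal liver and stress, 28.6% for cell cycle, 10.0% for Hox, 5.26% for architectural protein and 6.67% for housekeeping genes. For the markers of other cell types it was 0% (Kupffer cell), 13.3% (stellate cell), 11.1% (endothelial), 12.5% (cholangiocyte) and 33.3% (lymphocyte).

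PPARg was compared between genotypes to ask where its called sites differ in KO liver. Many more sites were called in KO only than in WT only. Of 33952 regions, 6070 were called in both KO and neither WT, 356 in both WT and neither KO, and 10131 in all 4. Covered length was 6.90 and 8.996 Mb in WT and 20.8 and 21.1 Mb in KO. The KO mean was 2.63 times the WT mean, so a greater covered length at a gene does not by itself set that gene apart. WT 4 was made with another library kit, and among the 3 libraries of 1 kit the counts were 7776 KO-only, 1309 WT-only and 11841 shared. With all lists shortened to equal length the counts were 1940, 1081 and 8579. Without KO 7 or KO 8 the KO-only count was 11839 or 12350, and the WT-only count was 1309 without WT 4, 1433 without WT 2, 759 without KO 7 and 566 without KO 8.

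The fatty acid translocase gene Cd36, with 10 kb either side of its span (chromosome 5, 17781690 to 17888959), held 4 and 5 PPARg peaks over 1599 and 1912 bp in WT and 12 and 11 peaks over 10764 and 13175 bp in KO. Pparg itself had 2486 and 1903 bp covered in WT and 4914 and 5896 bp in KO. The lipid droplet gene Plin2 had 2378 and 2507 bp in WT and 3267 and 3383 bp in KO, and Fabp4, a fatty acid carrier, had 569 and 910 bp against 1120 and 1531 bp. Set against the ratio of 2.63 over the whole lists, Pparg, Plin2 and Fabp4 rose by less and Cd36 by more. The KO-only sites with the best rank lay near Serp2, H4c11 and Mup10, 244 kb from Klf4, 196 kb from Gm765 and inside Pde5a, Eif3m, Prpsap1, Rapgef6 and Pard3. The Serp2 site (chromosome 14, 76520076 to 76521484) had fold enrichments of 28.0 and 34.2. Shared sites near Polr3gl, 53.0 kb from Abcd3 and inside Slc22a23 and Eci2 had higher fold enrichments in both KO than in both WT libraries. At the Polr3gl site (chromosome 3, 96570703 to 96577856) the folds were 48.2 and 87.1 in WT and 252 and 225 in KO. The shared site with the best rank, 1035 kb from Lrrc4c, had folds of only 4.68 to 6.08 in the 4 libraries. Blacklisted regions had not been removed from these lists, so whether it is a PPARg site is in doubt. The WT-only sites with the best rank lay 61.1 to 320 kb from Alkbh8, Pex2, Axin2, Vmn1r238 and Samd9l, with folds of 2.78 to 6.09. These folds were about as low as at the site near Lrrc4c, so whether they are PPARg sites is likewise in doubt.

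KO-only PPARg sites were concentrated at genes of hepatocyte metabolism, as were sites shared by all 4 libraries. A KO-only site lay within 10 kb of 20 of the 28 genes of fatty acid oxidation and ketogenesis, against 19.1% of other genes (odds ratio 10.6, adjusted p = 4.5e-08 by one-sided Fisher's exact test across genes). The share was 60.7% for hepatocyte identity (odds ratio 6.55, adjusted p = 1.3e-05), 57.7% for xenobiotic metabolism (5.77, adjusted p = 8.5e-05), and 59.1% for bile acid and cholesterol metabolism (6.11, adjusted p = 0.00017). It was 53.6% for PPARG targets and lipid droplet genes (4.88, adjusted p = 0.00017) and 54.2% for fatty acid and triglyceride synthesis (5.001, adjusted p = 0.00038). Ppara, the receptor that drives fatty acid oxidation, had 12540 and 13379 bp covered in WT and 26541 and 29425 bp in KO. Cpt1a, the gate of mitochondrial fatty acid uptake, had 4208 and 6290 bp against 9861 and 9918 bp. Alb (albumin) had 1366 and 508 bp against 5505 and 4614 bp, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 761 and 1759 bp against 3694 and 6354 bp. Fasn, the fatty acid synthase, had 752 and 477 bp against 2386 and 2169 bp, and Cyp2b10, a drug-metabolising enzyme, had 0 and 288 bp against 2813 and 2119 bp. Set against the ratio of 2.63 over the whole lists, Ppara and Cpt1a rose by less, and Alb, Cyp7a1, Fasn and Cyp2b10 by more.

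The other 11 lists did not pass against all other genes. Against backgrounds matched on gene length, a setting added after the data were seen, housekeeping genes passed as well (38.9% against 15.3%). They are not specific to liver. The share with a KO-only site was 38.9% for housekeeping (adjusted p = 0.101), 35.7% for architectural protein, 28.6% for fetal liver and stress and 15.0% for cell cycle genes. It was 23.5% for endothelial, 20% for cholangiocyte, and 10.5% for both Kupffer cell and lymphocyte markers. No gene of the Hox, protocadherin or stellate cell lists had one. A PPARg site in any library was also more frequent at these metabolic genes: all 28 genes of the oxidation list had one, against 46.2% of other genes, and 8 lists passed. Shared sites were enriched at the same 6 lists, each time more strongly than KO-only sites, and all 28 oxidation genes had one. Their odds ratio was 86.1 for hepatocyte identity, 22.3 for fatty acid synthesis and 20.2 for bile acid and cholesterol genes. It was 8.64 for xenobiotic and 7.96 for PPARG target genes. Fetal liver and stress genes passed for shared sites as well (47.6% against 23.9% of other genes, odds ratio 2.89, adjusted p = 0.037 by Fisher's exact test). The concentration is therefore not particular to KO-only sites. With lists of equal length, 3 of the 6 lists passed for KO-only sites. Fatty acid oxidation (odds ratio 3.37, adjusted p = 0.0674), fatty acid synthesis (2.47, adjusted p = 0.315) and xenobiotic metabolism (2.25, adjusted p = 0.315) did not, by Fisher's exact test.

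**Figure D2:**
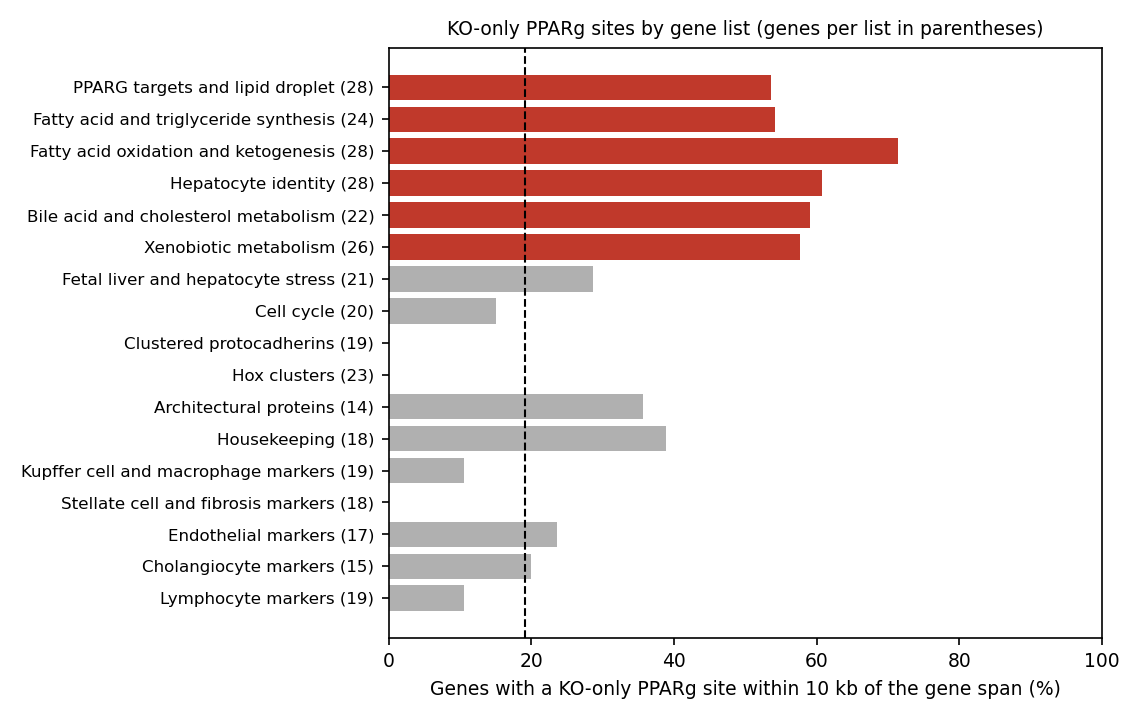
Bars give the percentage of genes in each of the 17 lists with a KO-only PPARg site within 10 kb of the gene span, red for lists past the adjusted threshold. The dashed line gives the percentage among genes outside a list, as the median over the lists. The 6 red bars lie between 53.6% and 71.4%, against 19.1% of other genes.

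KO-only PPARg sites were set against the other marks. They overlapped a lost CTCF site less often than shared PPARg sites did (0.445% against 0.948%, odds ratio 0.467, adjusted p = 0.00029), and a retained CTCF site less often as well (2.70% against 5.25%, odds ratio 0.501, adjusted p = 2.6e-15). H3K27ac regions called in all 3 KO and no WT held 60 KO-only and 16 shared PPARg sites (odds ratio 6.31, adjusted p = 2.4e-13). With H3K27ac lists of equal covered length they held only 6 and 2. Regions called in all 3 WT and no KO held 3 KO-only and 9 shared sites (odds ratio 0.556, adjusted p = 0.553). Any H3K27ac region overlapped 79.4% of KO-only and 96.8% of shared sites (odds ratio 0.129, adjusted p = 2.8e-280). These p come from two-sided Fisher's exact tests across sites, which are not independent replicates. KO-only sites were weaker than shared sites, with a median percentile of 38.3 against 78.4 in the KO lists.

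H3K27ac was compared to ask where active chromatin differed between genotypes. Of 57360 regions, 22736 (39.6%) were called in all 6 libraries. Regions called in all 3 KO and no WT numbered 620, and those called in all 3 WT and no KO numbered 99. The KO-only regions lay within 5 kb of the spans of 404 genes, among them Cd36, Cyp2b10, the cyclin gene Ccnb2, the stellate cell genes Des and Pdgfrb, the endothelial gene Eng and the T cell gene Cd3d. The WT-only regions lay within 5 kb of 67 genes, among them Prox1, a hepatocyte transcription factor, and Cyp7b1, an enzyme of bile acid synthesis. Wide WT-only regions lay at Mup7, Hsd3b5, Aox1, Slc22a28 and Slc13a2 and 29011 bp from Hsd3b2, and wide KO-only regions near Ms4a6b, Slc22a12 and Gimap3, 86785 bp from Oat and inside Matn2, Ptger4 and Sh2d3c. WT-only regions held a PPARg site of both WT more often than KO-only regions did (14.1% against 2.58%, adjusted p = 3.2e-05 by Fisher's exact test), whereas a KO-only PPARg site lay in 9.35% of KO-only and 3.03% of WT-only regions (adjusted p = 0.0655). A PPARg site of both KO lay in 14.4% and 18.2% (odds ratio 0.754, Fisher's exact adjusted p = 0.361). The excess of KO-only regions moved with the length of the lists. With lists of equal length the counts were 383 and 249, and with lists of equal covered length, a setting added after the data were seen, they were 35 and 262. Without KO 4 the counts were 719 and 530, and without KO 2 or KO 3 the KO-only regions numbered 2354 or 1412. Without WT 1 the counts were 965 and 281, without WT 2 they were 1193 and 169, and without WT 4 the WT-only regions numbered 299.

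At single genes, H3K27ac was measured as the percentage of the gene span with 5 kb either side that peaks covered (mean ± SD, n = 3 each). None of the 14877 genes passed an adjusted p of 0.05 in limma in either direction. At an unadjusted p under 0.05, 765 were higher and 158 lower in KO, and the median gene was 0.916 percentage points higher. That median was 0.00141 points without KO 4 and 1.66 without KO 2. It was −0.0480 points after division by total covered length and 0.166 with lists of equal covered length. In 1523 genes all 3 KO values lay above the WT values and in 234 all lay below, 11.8% together, where chance gives 10%. The gene nearest the threshold was Elovl3 (chromosome 19, 46131897 to 46135694), an elongase of very long chain fatty acids, with 38.4% ± 2.26 in WT and 6.71% ± 2.46 in KO (limma adjusted p = 0.106). The other lower genes named by the rule, none past the test, included 4 major urinary protein genes: Mup11 (48.3% ± 27.3 against 11.7% ± 0.884), Mup7 (27.2% ± 13.9 against 0%), Mup16 (40.8% ± 15.4 against 17.1% ± 5.22) and Mup14 (22.3% ± 6.80 against 3.72% ± 3.25). They also included Pitx3 (27.2% ± 1.33 against 8.05% ± 1.95), the neighbour of Elovl3 whose window holds the same lost peaks, the bile acid importer Slc10a1 (44.6% ± 17.995 against 29.4% ± 5.07), and the chemokine Cxcl1 (41.4% ± 5.02 against 26.4% ± 6.19). The fibrinogen chain Fgg had 73.6% ± 4.47 against 59.0% ± 9.66, and the steroid dehydrogenase Hsd3b5 had 25.5% ± 4.31 against 10.9% ± 1.765. Single libraries weighed on some: the difference at Slc10a1 was −15.2 points and −4.83 without WT 2, at Mup11 −36.6 and −22.9 without WT 4, at Mup16 −23.7 and −15.4 without WT 4, and at Fgg −14.6 and −9.64 without KO 3.

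The higher genes named by the rule, also none past the test, were led by the immediate early gene Egr1 (49.0% ± 16.2 in WT, 81.6% ± 9.09 in KO). Tmsb10 had 15.6% ± 7.34 and 46.5% ± 21.4, Ly6a (the surface antigen Sca-1) 31.3% ± 3.77 and 61.8% ± 20.03, and Rem1 20.2% ± 10.2 and 50.6% ± 11.3. Ms4a6b had 6.59% ± 6.74 and 36.7% ± 16.6, Crip1 38.5% ± 17.0 and 68.0% ± 8.59, and Plvap, an endothelial diaphragm protein, 36.0% ± 2.06 and 63.7% ± 17.8. Tac4 had 16.1% ± 4.85 and 42.0% ± 15.8, Tmem200b 47.6% ± 6.40 and 73.2% ± 9.12, and the glutathione transferase Gstm3 15.1% ± 3.36 and 39.7% ± 7.53. The difference at Ly6a was 30.5 points and 19.02 without KO 4. Within 1 kb of its marked end, Plvap went the other way (KO minus WT −122 bp). Pparg had 12.7% ± 0.803 in WT and 13.0% ± 3.31 in KO. Ctcf had 3.67% ± 0.0593 and 5.87% ± 1.10. The balance of higher and lower genes moved with the scaling. At an unadjusted limma p under 0.05 there were 701 higher and 892 lower genes after division by total covered length, and 628 and 521 with lists of equal covered length. Without KO 4 there were 560 and 542, without KO 2 there were 1964 and 86, and without KO 3 there were 742 and 91. Without WT 1 there were 491 and 155, without WT 2 there were 572 and 86, and without WT 4 there were 367 and 167.

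**Figure D3:**
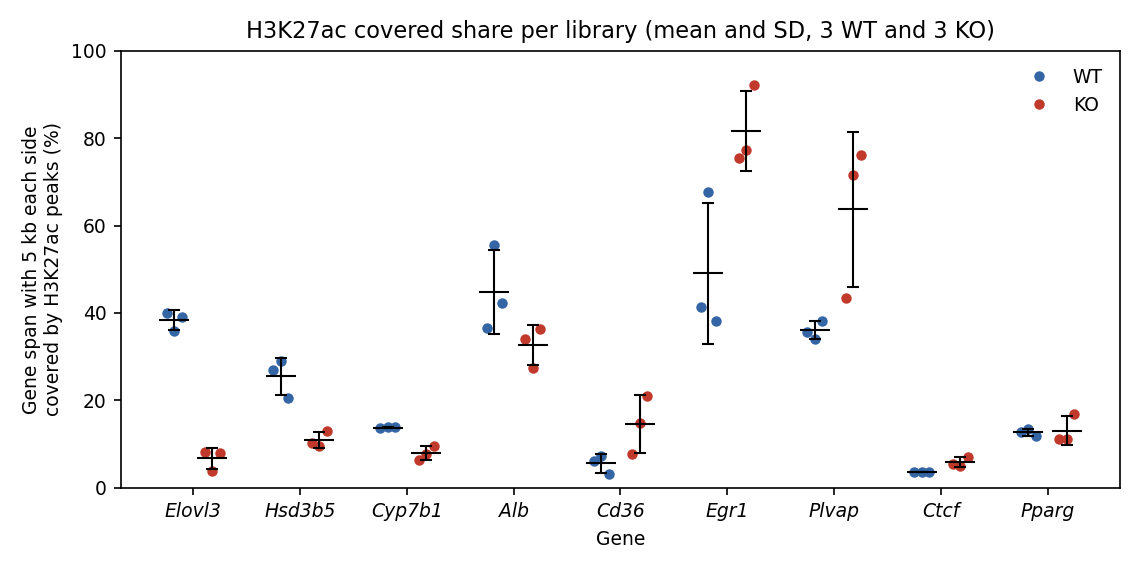
Points give the percentage of the span of 9 genes, with 5 kb either side, covered by H3K27ac peaks in each of 3 WT (blue) and 3 KO (red) libraries, with bars for mean and SD. For Elovl3 all KO values (3.88% to 8.20%) lie below all WT values (35.8% to 40.1%), and no gene passed the adjusted threshold.

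As a group, hepatocyte identity genes carried less H3K27ac in KO relative to other genes. Coverage was lower for 19 of the 27 measured members, by a mean of −3.08 and a median of −2.17 points (limma camera with a preset correlation, adjusted p = 6.1e-09). With an estimated correlation the list did not pass (camera p = 0.0903, adjusted p = 0.914). Alb had 44.8% ± 9.66 in WT and 32.7% ± 4.62 in KO, Apoa2 98.9% ± 1.88 and 93.8% ± 10.8, and Apob 16.4% ± 3.39 and 16.5% ± 4.02. Bile acid and cholesterol genes were lower as well (13 of 22, mean −2.07 and median −0.526 points, adjusted p = 2.3e-07), but did not pass with an estimated correlation (camera p = 0.108, adjusted p = 0.914). Cyp7b1 had 13.8% ± 0.0523 and 7.89% ± 1.61, Cyp8b1, which makes the cholic acid branch, 100% in all 3 WT and 88.4% ± 11.7, and Cyp7a1 60.8% ± 20.05 and 58.5% ± 17.1. With fry, which asks whether the members move together without reference to other genes, no list passed (adjusted p = 0.676 or more). Both lists passed with camera without each library in turn, KO 4 included, but within 1 kb of the marked gene ends hepatocyte identity did not (adjusted p = 0.135). The covered share cannot pass 100%, so well covered genes had less room to rise. Its mean in WT was 57.0% for hepatocyte identity and 34.7% for bile acid and cholesterol genes. Camera did not match the other genes on coverage, so this limit may add to the differences relative to other genes.

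The remaining 15 lists did not pass with camera in the main values. Stellate cell and fibrosis markers passed as higher after division by total covered length, with lists of equal length, within 5 kb of the marked end, with genes without variation kept, with the replicate number as a block, without WT 1 and without KO 3. Fatty acid and triglyceride synthesis passed as lower after division by total covered length, with lists of equal length or equal covered length, with the block, without WT 4 and without KO 3. Cell cycle genes passed as higher with genes without variation kept and without WT 1, protocadherins as higher with a −log10 q of at least 5 and with the block, and fatty acid oxidation as lower with the block. These calls rest on the preset correlation. In the main values the camera p with an estimated correlation was 0.439 for stellate cell, 0.443 for fatty acid synthesis, 0.412 for cell cycle, 0.710 for protocadherin and 0.676 for fatty acid oxidation genes (adjusted p = 0.942 for each). For fatty acid and triglyceride synthesis 15 members were higher and 9 lower (adjusted p = 0.0595, mean −0.821 but median 0.977 points, with −31.6 points at Elovl3). Among fatty acid oxidation genes 18 were higher and 10 lower, among PPARG targets and lipid droplet genes 21 and 6, and among xenobiotic genes 13 and 12. Cd36 had 5.57% ± 2.18 in WT and 14.6% ± 6.58 in KO (difference 8.98 points, 5.77 without KO 4), and Plin4 45.4% ± 2.83 and 61.0% ± 12.7. Stellate cell and fibrosis markers were higher for 15 of 16 (adjusted p = 0.0581). Des had 3.11% ± 3.29 and 16.0% ± 5.10, and Pdgfrb 12.1% ± 5.31 and 26.5% ± 7.58. Higher values were also found in 17 of 19 cell cycle genes (adjusted p = 0.0846), 11 of 12 lymphocyte, 13 of 16 endothelial, 10 of 16 Kupffer cell and 7 of 9 cholangiocyte markers. The counts were 8 of 8 for protocadherins and 5 of 5 for Hox genes, lists whose neighbouring windows share peaks. They were 10 of 14 for architectural proteins, 13 of 18 for housekeeping and 14 of 18 for fetal liver and stress genes. Over all genes no list member passed. Adjusted over the list alone, 1 gene passed in each of 5 lists with limma: Elovl3 (fatty acid synthesis), Vnn1 (fatty acid oxidation, 13.8% ± 0.628 and 9.56% ± 0.735), Cyp7b1 (bile acid), Gstp1 (xenobiotic, 52.8% ± 1.55 and 64.6% ± 3.56) and Spp1 (cholangiocyte, 0.826% ± 1.43 and 8.99% ± 2.75), and 0 in the other 12 lists.

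H3K27ac change was also compared between genes with and without a lost CTCF site. In 1773 genes with a lost site within 5 kb the mean change was 1.43 points (SD 3.08), and in 6340 genes with retained sites only it was 1.89 points (SD 3.74). The difference was −0.454 points (two-sided permutation test across genes, p = 1e-05, the smallest that 100000 resamples can give). Genes are not independent replicates, and regrouping the 6 libraries gave a difference of up to 0.464 points. The 2 groups of genes were not matched on gene length, although the measure is a share of the gene span. After division by total covered length the 2 means were −0.576 and −0.373 points. The difference was −0.202 points (permutation p = 0.048), with up to 0.248 on regrouping. With lists of equal covered length, a setting added after the data were seen, the means were 0.0931 and 0.471 points. The difference was −0.378 points, with up to 0.363 on regrouping. Within 25 kb it was −0.343 points, with up to 0.247 on regrouping. The sign of both means thus moved with the scaling, and 10 splits are too few for a share under 0.05. Lost sites lay in KO-only H3K27ac regions at 6 places (0.202%) and in WT-only regions at 2 (0.0675%), and retained sites at 27 (0.169%) and 4 (0.0251%).

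H3K4me3 was compared in 1 WT and 1 KO library, without a test. The libraries shared 12566 regions, with 2823 in WT alone and 2608 in KO alone. Peaks covered 21.7 Mb of the genome in WT and 19.1 Mb in KO. Around gene ends, Elovl3 had 2263 bp covered in WT and 0 bp in KO, and Leap2, which encodes a liver peptide hormone, 2055 and 0 bp. Rabepk (3079 and 1321 bp), Apoc4, an apolipoprotein (2766 and 1027 bp), and Aff4 (3245 and 1707 bp) were also lower in KO. The peak that Aff4 lost is the one counted at Leap2, its neighbour. The endothelial transcription factor Sox18 had 0 and 1561 bp, Ppp1r3d 0 and 1438 bp, Pde4a 0 and 1405 bp, Usp43 0 and 1405 bp, and the endothelial receptor Gpr182 1063 and 2394 bp. Endothelial markers with H3K4me3 numbered 9 in WT and 13 in KO, and their mean gain of 319 bp lay at the 100th percentile of 10000 random lists of genes with like covered length. Hepatocyte identity genes had a mean of 1320 bp in WT and 1073 bp in KO, at percentile 0, and bile acid and cholesterol genes 1465 and 1165 bp, at percentile 0.02. Housekeeping genes, which are not specific to liver, had 1633 and 1393 bp, at percentile 0.68. The percentile was 21.5 for PPARG targets, 0.48 for fatty acid synthesis, 46.9 for fatty acid oxidation, 0.87 for xenobiotic, 25.01 for fetal liver and stress and 93.2 for cell cycle genes. It was 37.4 for architectural proteins, 18.9 for Kupffer cell, 92.9 for stellate cell, 49.9 for cholangiocyte and 80.5 for lymphocyte markers.

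H3K27me3, in 1 library each, was the sparsest mark, with 3482 shared regions, 4201 in WT alone and 5597 in KO alone. Only 117 WT and 269 KO peaks reached a −log10 q of 3. Covered length over the genome was 4.01 Mb in WT and 6.25 Mb in KO. The largest gains in KO were at Cdh22 (7011 and 16518 bp), Pax2 (13512 and 22591 bp), Pax6 (5181 and 13622 bp), Pax7 (6943 and 15290 bp) and Hoxd3 (8967 and 16917 bp). Less was covered at Auts2 (7751 and 1875 bp), Cyp3a41a, a cytochrome P450 (4098 and 0 bp), Sult2a1, a sulfotransferase (4177 and 430 bp), Kcns3 (5105 and 1910 bp) and Slco4a1 (3039 and 124 bp). Of the 23 Hox genes 23 were marked in WT and 22 in KO (mean 3698 and 5771 bp), and 14 protocadherins were marked in both (mean 2000 and 1514 bp). Neighbouring members of both lists count the same peaks several times, so no percentile is given for them in either mark. Xenobiotic genes had a mean of 209 and 16.5 bp (percentile 0.05), most of it from Sult2a1, with 753 and 0 bp at Cyp2b9, 507 and 0 bp at Cyp2b10 and no mark at the others. Cholangiocyte markers had a mean of 65.7 and 441 bp (percentile 99.3), with 1 marked in WT and 5 in KO. The percentile lay between 3.41 and 95.6 for the other 13 lists, with no marked gene among the housekeeping and architectural lists.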

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

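The alternatives were fixed in advance except lists of equal covered length, a common PPARg threshold, windows at gene ends, 5 kb around the marked end and length-matched backgrounds, which were chosen after the data were seen. Over 83 results, 737 alternative values were computed, of which 651 kept their direction and side of the threshold or stayed within 1.5 times, 12 lost a call, 11 gained one, 62 moved and 1 reversed. Of the 177 values of the main results 116 were the same, and of the 560 of single genes and lists 535. For the named H3K27ac genes, 318 of 319 values kept their direction and 0 passed the adjusted threshold. The exception was Plvap within 1 kb of its marked end (−122 bp). Odds ratios that were not finite (31) were left out. Unless the construction shows it, as where fewer peaks or libraries enter, the cause was not tested.

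With a −log10 q of at least 10, 32 CTCF sites were gained, and PPARg had 3592 KO-only, 82 WT-only and 3543 shared sites. With an overlap of 50%, 105 CTCF sites were gained and 619 PPARg sites were WT-only. With lists of equal length, 649 CTCF sites were lost (3.99%) and 390 gained. PPARg then had 1940 KO-only and 1081 WT-only sites, 3 lists passed for KO-only sites, and H3K27ac had 383 KO-only and 249 WT-only regions. Among the tagmentation libraries 1309 PPARg sites were WT-only. With lists of equal covered length H3K27ac had 35 KO-only and 262 WT-only regions. With a −log10 q of at least 5, H3K27ac had 5 KO-only and 27 WT-only regions, H3K4me3 had 1579 WT and 1059 KO private regions, and H3K27me3 had 15 shared, 9 WT and 13 KO private regions, so its peaks were near the calling limit. In limma, 1 gene was higher in KO within 1 kb of the marked end and 1 was lower with a −log10 q of at least 5. The number of H3K27ac lists past camera was 1 within 1 kb of the marked end, and 4 after division by total covered length, with lists of equal length and with genes without variation kept. With the replicate number as a block it was 6, with 0 genes past the threshold in either direction and 221 higher and 53 lower at an unadjusted p under 0.05. Deviations from the genotype means gave correlations of −0.200 and −0.172 between WT and KO libraries of the same number, so pairing is not shown.

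Over the fits that each left out 1 library, lost CTCF sites ranged from 3927 to 7130 (17.8% to 26.2%) and gained sites from 97 to 732. The odds ratio for H3K27ac at lost sites ranged from 0.751 to 0.939, and that for H3K27me3 from 0.526 to 0.681. KO-only PPARg sites ranged from 7776 to 12350 and WT-only sites from 566 to 1433. KO-only H3K27ac regions ranged from 719 to 2354 and WT-only regions from 120 to 530, and 2 to 4 H3K27ac lists passed. Fewer libraries loosen the rule for each class. Read depth, unknown here, limits every call near a threshold.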

Other observations

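Of the tests in this part, the one that sets PPARg against H3K27ac with lists of equal covered length was written down before its result was seen, and all others were chosen after the result they concern had been seen. Lists of 24 male-biased and 30 female-biased mouse liver genes were also typed after the first tables were seen, when Elovl3, Cyp7b1, Srd5a1 and C8b had been noticed in the former and Cd36 had been seen in the latter. H3K27me3 at the latter was looked at after its changes at Cyp3a41a, Sult2a1, Cyp2b9 and Prom1 had been seen. The named members of these lists were chosen after their values were seen.

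Male-biased liver genes, many of which depend on the pulsed growth hormone of males, carried less H3K27ac in KO. Of the 21 measured, 17 were lower, by a mean of −6.63 points against 1.69 points for all genes (limma camera p = 8.1e-22, and p = 0.00636 with an estimated correlation). Without the 4 noticed first, 13 of 17 were lower, by a mean of −5.01 points (camera p = 0.0128 with an estimated correlation). Mup7 had 27.2% ± 13.9 in WT and 0% in KO (n = 3 each), Hsd3b5 25.5% ± 4.31 and 10.9% ± 1.765, Slco1a1 16.4% ± 2.55 and 8.16% ± 4.67, and Srd5a1, a steroid reductase, 31.1% ± 1.07 and 22.0% ± 1.23. All 3 KO values lay below the WT values in 11 of the 21 and above them in 1, Gstp1, where chance gives 10% for both directions together. The 11 include the 4 genes noticed first, so they are not free of the values that prompted the list. Another list held 4 of the 24 genes: Elovl3, Cyp7b1, Cyp2d9 and Gstp1. With the replicate number as a block the camera p with an estimated correlation was 0.0917.

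The other marks, with 1 library each and no test, showed related values. H3K4me3 was found at 17 male-biased genes in WT and 13 in KO (mean 1712 and 1101 bp). Its covered length over the genome was also lower in KO, 19.1 Mb against 21.7 Mb in WT. Hepatocyte identity, housekeeping and female-biased genes lost H3K4me3 coverage as well, so a fall is not particular to male-biased genes. H3K27me3 was found at 10 female-biased genes in WT and 5 in KO, with a mean of 688 and 181 bp. Cyp3a41a had 4098 and 0 bp, A1bg 2641 and 0 bp, Cyp3a16 2839 and 842 bp, Cyp2b13 1150 and 0 bp, Cyp3a44 1167 and 0 bp and Cyp2b9 753 and 0 bp, while Cux2 kept 2687 and 2462 bp and Prom1 had 0 and 1177 bp. Female-biased genes as a group did not differ in H3K27ac (16 of 22 higher, camera p = 0.604, and p = 0.876 with an estimated correlation), although Cyp2a4, Cyp2b13, Cyp17a1 and Cd36 had all 3 KO values above the WT values. Cyp2a4 had 5.04% ± 4.36 in WT and 23.5% ± 13.6 in KO.

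For the lower H3K27ac at male-biased genes, the tables argue against female animals among the KO, since each of 4 Y-linked genes was covered in each KO library (lowest value 693 bp). A loss of hepatocyte chromatin in general stays open. The change was −6.08 points from the other genes of the 5 hepatocyte lists (permutation p = 5e-05). Without the 4 noticed first it was −4.47 points (permutation p = 0.0014). From the hepatocyte identity list it was only −3.55 points, with those 4 included (permutation p = 0.091). A shift of the sex-biased programme stays open: the mean H3K27me3 change of female-biased genes lay at percentile 0 of 10000 random lists of like covered length, with and without the 4 seen first, in 1 library per genotype. The Y-linked check covered the H3K27ac libraries alone and neither H3K27me3 list held a peak on X or Y, so a female KO animal in that mark could give the same percentile of 0. The H3K4me3 of female-biased genes went both ways, with 9 marked in WT and 13 in KO but a mean of 690 and 506 bp (percentile 0.49).

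For the excess of KO-only PPARg sites, the library kit is argued against as the sole cause. Among the 3 libraries of 1 kit, with 1 WT library among them, KO-only sites were 5.94 times as many as WT-only sites. These 3 libraries also share the calling threshold and the label of fasted males. Longer KO lists, whether from depth, from a more efficient precipitation or from more binding, could account for it, because KO-only sites made up 71.0% of the weakest and 0.255% of the strongest 10% of sites. They may not be the whole cause, since lists of equal length still gave 1940 KO-only against 1081 WT-only sites. PPARg gained together with H3K27ac in KO cannot be told apart from longer lists. KO-only PPARg sites lay in KO-only rather than WT-only H3K27ac regions with an odds ratio of 11.3 against shared sites (Fisher's exact p = 0.00043), but with H3K27ac lists of equal covered length it was 3.78 (Fisher's exact p = 0.14), from 6 and 23 against 2 and 29 sites.

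For the CTCF sites kept in KO, the loss of 60.9% of the weakest and 0% of the strongest 10% of sites is what a calling threshold would give if signal fell at all sites, so the share of sites lost may say little about the share of signal lost. CTCF from liver cells in which Alb-Cre is not active could also keep sites called and stays open. Sites at genes of the 5 hepatocyte lists were lost in 27 of 114 cases (23.7%) and at markers of 5 other cell types in 7 of 43 (16.3%), with an odds ratio of 1.60 (Fisher's exact p = 0.388). This comparison cannot decide it, because neither the cells that bind a site near a marker gene nor the cells in which Cre acted were measured.

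The 6 H3K27ac libraries form 10 splits, too few for a share under 0.05. The real split gave 719 regions of 1 side only (highest other 668, as many in 1 of 10), 0 genes past the adjusted threshold (highest other 0, as many in 10) and 923 genes at an unadjusted limma p under 0.05 (highest other 1354, as many in 3). With lists of equal length it gave 632 regions (highest other 337), but with lists of equal covered length 297, fewer than 3 other splits (highest 880). In the main values it gave 2 lists past camera (highest other 5, as many in 6), and for male-biased genes a mean of −8.31 points from all genes (highest other 4.59, as large in 1).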
